A study of Mus musculus with 2 samples.

How the data were processed

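RNA from 2 cultures of mouse calvarial cells, 1 at day 5 and 1 at day 12 of osteoblast differentiation, was converted to biotin-labelled cRNA and hybridised to 1 Affymetrix array each, per the labels' protocols. The submitters' processing notes name GCOS 1.4 and MAS5, and give no further settings. The authors deposited 1 table of signal intensity for 45101 probe sets on a linear scale, and no detection call was used here. The mean after trimming 2% of probe sets at each end was 200.0 on both arrays, which shows that each array was scaled to the same target. Such scaling sets the centre of the 2 arrays equal and cannot show a change in total RNA per cell. The genome build was not given in the sources used here, so no coordinates are printed.

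Probe sets were named from the platform annotation. Of 45037 probe sets other than the 64 controls, 34945 had 1 gene symbol, 932 had several and 9160 had none. The symbol was updated through the Entrez number for 34741 of them in a table of the assembly GRCm38.p6, and the annotation's symbol was kept otherwise. Probe sets with several symbols or none were not named. Some members of the gene lists had no probe set with 1 symbol and were not analysed here.

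For each of 18193 genes the probe set with the highest mean log2 signal was used. Deposited values were used without further normalisation. Each array's 60th percentile over all probe sets but the controls served as its floor, and 10479 genes with at least 1 value at or above it were counted as measured, 9810 of them on both arrays. Values below the floor were raised to it before the log2 ratio of day 12 over day 5 was taken, which understates the change of such genes. Of the genes counted past 2-fold, 69 higher and 32 lower ones were bounds of this kind. Short probes on arrays cross-hybridise between near-identical genes, so values of Lyz1 and Lyz2, of Aldh1a7 and its paralogs and of Fc receptor genes are uncertain in their assignment. Signals near the top of the scale can be compressed.

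With 1 array per day there was no test, and a gene was counted as higher or lower where its ratio was at least 2-fold. Before the data were examined, 35 gene lists, the floor, the threshold, the alternatives and the rule for named genes were fixed. The rule names the 12 genes with the largest ratio in each direction among genes above the floor on both arrays whose measured probe sets all moved the same way, the 5 with the largest bound in each direction, up to 4 members of each list with the largest ratio, list members past 2-fold, and any member of the mineralisation and transcription factor lists. Sost, Fgf23, Ldha, Adm, Eno2, Col1a1, Col2a1, Comp, Sox6, Axin2, Gli1, Tnfsf11, Tnfrsf11b, Itgam, Adipoq, Pparg, Acta2, Mki67, Top2a, Loxl3, P4ha3, Loxl1, Cx3cr1, Aif1, Fos and Egr1, and the genes of the closing section outside the 35 lists, were chosen after their values were seen. For each list the median log2 ratio was set against the medians of 10000 random lists of the same size, drawn from measured genes matched by decile of mean log2 signal, and the same was done under each alternative. The percentile describes these 2 arrays and is not a p-value. Intervals of the share of members higher at day 12 are exact 95% Clopper-Pearson intervals and cover the number of genes only. Bootstrap 95% intervals resample the members of a list as if they were independent, and leave out differences between cultures.

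Array quality was read from the control probe sets. Hybridisation controls above the floor had a mean log2 ratio of 0.08 ± 0.07 (SD over 18 probe sets) and poly-A controls of -0.06 ± 0.13 (SD over 24 probe sets). The 3' over 5' signal ratio was 1.25 at day 5 and 1.22 at day 12 for Actb, and 0.736 and 0.799 for Gapdh. Across the 17215 probe sets above the floor on both arrays, log2 signals correlated with Pearson r = 0.963, a correlation across probe sets, which are not independent replicates. The difference between 2 probe sets of 1 gene was a median of 0.25 in the dimmest of 4 equal groups of genes by signal and 0.12 in the brightest, so bright genes are measured more closely. The number of arrays limits the precision of every value.

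The alternatives were median centring, quantile normalisation, loess on signal, floors at the 50th and 75th percentile, a pseudocount in place of the floor, the median over a gene's probe sets, leaving out probe sets of shared sequence, and thresholds of 1.5-fold and 3-fold. The code was tested on simulated data made from the real signals with a spread of 0.25 in the log2 ratio above the floor. Changes were planted only in genes well above the floor, and no difference between cultures was simulated. The code counted 100% of genes planted at a log2 ratio of 1.5 and 98.0% of those at -1.5, and counted 23 of 10195 unchanged genes as past 2-fold. These shares are therefore not error rates of the counts on the real arrays. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.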

Results

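Gene expression was measured in primary mouse osteoblast cultures at 2 times of differentiation. The cells came from the calvariae (skull roof bones) of newborn mice, were depleted of cells carrying CD11b, a myeloid surface protein, and were cultured with ascorbic acid and β-glycerophosphate, which allow collagen deposition and mineral formation in culture. Total RNA was taken after 5 days and after 12 days, and each sample was hybridised to 1 Affymetrix mouse array with 45101 probe sets. There was 1 array per day, so no replicate error, standard error or p-value could be given for any value below, and every difference compares these 2 arrays. The deposited signal had a median of 19.7 at day 5 and 19.6 at day 12, and reached 15422 and 16944 at its highest. A floor was set at the 60th percentile of each array, which was a signal of 46.6 at day 5 and 44.8 at day 12. Where a gene lay below the floor on 1 array its fold is a bound and is written as "at least". The only repeat measurement was that of several probe sets for 1 gene. In 4446 genes with 2 or more measured probe sets, the log2 ratios of the 2 brightest differed by a median of 0.17, which covers probe error but not differences between cultures. That median was 0.32 in genes at least 2-fold higher at day 12 and 0.23 in genes at least 2-fold lower.

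The comparison of day 12 with day 5 asks which genes change as calvarial osteoblasts mature. The genes furthest above their day 5 signal at day 12 included genes of bone mineralisation and of glucose use and hypoxia, while those furthest below it included cartilage genes. Markers of other cell types moved as well, with a median log2 ratio of 1.42 for myeloid and -1.29 for chondrocyte markers. Of 10479 genes measured, 373 (3.56%) were at least 2-fold higher at day 12 and 181 (1.73%) were at least 2-fold lower, and 98 and 8 of them differed by at least 4-fold. The median log2 ratio of all measured genes was -0.05, with quartiles of -0.27 and 0.17. Among genes above the floor on both arrays, Ndufa4l2, which encodes a mitochondrial protein induced by low oxygen, was the furthest up, with a signal of 75.2 at day 5 and 1909 at day 12 (25.4-fold). It was followed by Dmp1, an acidic bone matrix protein of osteocytes (20.2-fold), Kbtbd11 (15.3-fold), Ifitm5, a membrane protein of mineralising osteoblasts (12.1-fold), and the small heat shock protein gene Hspb7 (11.9-fold). Ak4, a mitochondrial adenylate kinase, Fcgr2b, an immunoglobulin Fc receptor of myeloid cells, Aldoc, a glycolytic aldolase, and Vldlr, a lipoprotein receptor, were 11.3-fold, 11.2-fold, 11.1-fold and 10.2-fold higher, and Cd200 was 8.87-fold higher. These are ratios of the brightest probe set, and the lowest measured probe set gave a log2 ratio of 0.76 for Ak4, 0.99 for Vldlr, 1.24 for Kbtbd11, 1.52 for Hspb7 and 1.95 for Fcgr2b. From below the floor at day 5, Egln3, an oxygen-sensing prolyl hydroxylase, was at least 48.8-fold higher, Ptprz1 at least 21.3-fold, Ankrd37 at least 20.2-fold, the carbonic anhydrase gene Car9 at least 18.2-fold and Col13a1, a transmembrane collagen, at least 17.7-fold. These bounds are of the brightest probe set, and the other measured one gave a log2 ratio of 3.11 for Egln3 and 3.66 for Ptprz1. In the other direction Aldh1a7, an aldehyde dehydrogenase, was 6.40-fold lower at day 12, Col9a2 5.61-fold, Pcp4l1 4.18-fold, the Wnt receptor gene Fzd9 4.10-fold and Serpinb1a 3.83-fold. Otor, Ada (adenosine deaminase), AW551984, Txnip (an inhibitor of glucose uptake), Lrrc75b and Ccn5 were between 3.36-fold and 3.55-fold lower, of which Otor, Ada and Lrrc75b had log2 ratios of -0.87, -0.70 and -0.18 with the 75th percentile floor. Tmeff2 was at least 4.0-fold and Scrg1 at least 3.50-fold lower. A second measured probe set existed for 145 of the genes counted as higher and for 70 of those counted as lower. It moved in the same direction in 144 and 69 of them, and was itself past 2-fold in 103 and 42.

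**Figure D1:**
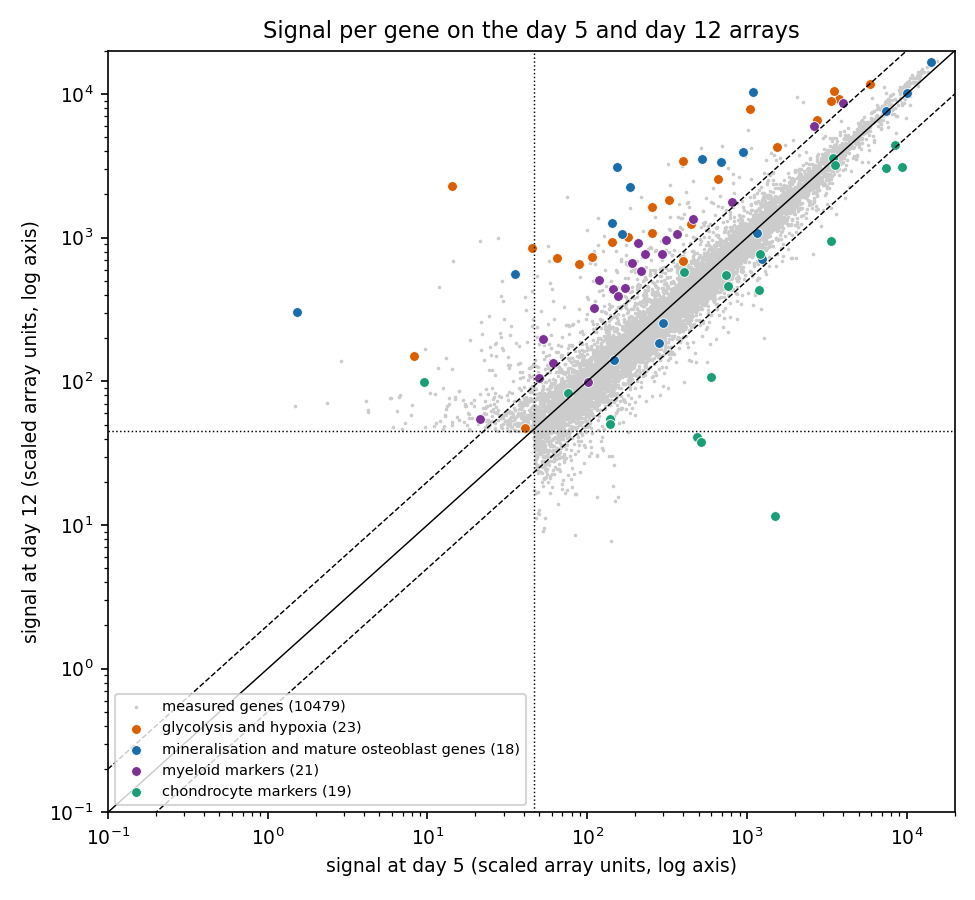
Signal of each of the 10479 measured genes at day 5 (x axis) and at day 12 (y axis), in scaled array units on log axes, with 1 array per day. The solid line marks equal signal, the dashed lines a 2-fold difference and the dotted lines the floor of each array (46.6 and 44.8). Coloured points are genes of 4 lists: 10 of 18 mineralisation genes, 20 of 23 glycolysis and hypoxia genes and 19 of 21 myeloid markers differ by at least 2-fold towards day 12, and 10 of 19 chondrocyte markers by at least 2-fold towards day 5.

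Genes of mineralisation and of the mature osteoblast were higher at day 12. Of 18 measured members of the list fixed for them, 10 were at least 2-fold higher, none was at least 2-fold lower and 8 lay between. Besides Dmp1 and Ifitm5, Ibsp, the bone sialoprotein gene, went from a signal of 1098 to 10334 (9.41-fold), and Alpl, the alkaline phosphatase that frees phosphate for mineral, from 684.1 to 3355 (4.90-fold). Phex, an endopeptidase of phosphate control, was at least 11.9-fold higher and Mepe, a matrix phosphoglycoprotein, at least 6.47-fold (a log2 ratio of 0.73 with the 75th percentile floor). The citrate transporter gene Slc13a5 was 8.75-fold higher, Smpd3, a sphingomyelinase needed for mineral formation, 6.43-fold, and the parathyroid hormone receptor gene Pth1r 4.18-fold. The lowest measured probe sets of Slc13a5 and Smpd3 gave log2 ratios of 1.46 and 1.63. Panx3 was 6.78-fold higher by its brightest probe set, but its other measured probe set gave a log2 ratio of only 0.28. The members brightest at day 5 differed little, with log2 ratios of 0.24 for Sparc, 0.02 for Mgp and 0.02 for Cdh11. Signals near the top of the scale can be compressed. The phosphate transporter gene Slc20a1 had a log2 ratio of -0.82, Slc20a2 -0.24, Fam20c -0.62, Ank -0.09 and Vdr -0.05. The other measured probe sets of Slc20a2 and Fam20c went the other way, at 0.28 and 0.07. The list's median log2 ratio was 2.18, at percentile 100 of 10000 random lists of equal size and signal. The median lies beside a gap between Pth1r (2.06) and Sparc (0.24), and was 1.61 with the 75th percentile floor and 1.17 without probe sets of shared sequence.

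**Figure D2:**
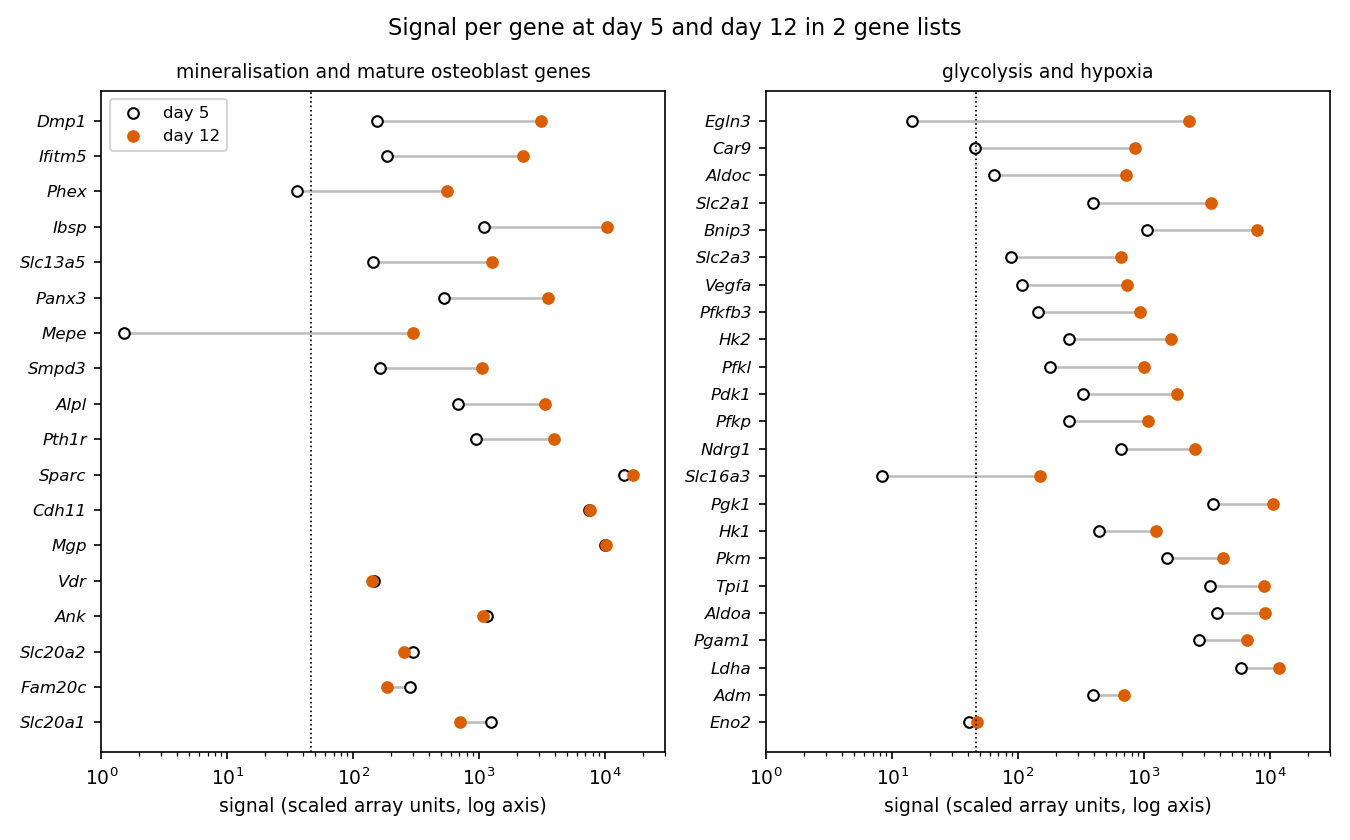
Signal of each measured member of the mineralisation list (left) and of the glycolysis and hypoxia list (right) at day 5 (open circles) and day 12 (filled circles), in scaled array units on a log axis, 1 array per day. The dotted line marks the day 5 floor of 46.6. Dmp1 and Egln3 stand at the top with the largest ratios, and the day 12 value lies above the day 5 value in 13 of the 18 and 23 of the 23 genes.

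Transcription factors of the osteoblast lineage split. Mef2c was 7.99-fold higher at day 12 in the brightest of its 5 measured probe sets, Sp7 (osterix), which is required for osteoblast formation, was 3.45-fold higher and Dlx5 2.67-fold higher. The homeobox genes Msx2 and Msx1 were 2.67-fold and 2.05-fold lower, of which Msx1 was less than 2-fold lower under median centring, after loess, with a pseudocount and without probe sets of shared sequence. The other 12 of 17 measured members differed by less than 2-fold, among them Fosl1 at a log2 ratio of 0.76, Fosl2 at 0.67, Dlx3 at 0.57, Atf4 at 0.53, Dlx6 at 0.24, Prrx1 at -0.05, Twist2 at -0.09, Snai2 at -0.12, Twist1 at -0.18, Zfp521 at -0.24, Prrx2 at -0.29 and Lef1 at -0.61, where those of Dlx3, Twist2 and Lef1 are bounds. The median of the 17 was -0.05 (percentile 41.6), and was above 0 under median centring and after loess. Of 14 measured osteocyte genes, 5 were at least 2-fold higher, which were Dmp1, Phex, Mepe, Dkk1 and Irx5 (2.26-fold), and none was at least 2-fold lower. Sost and Fgf23, products of mature osteocytes, lay below the floor on both arrays, with signals of 0.98 and 41.5 for Sost and 12.1 and 9.07 for Fgf23. With the 50th percentile floor Sost was measured and counted as at least 2-fold higher. The median of the list was 0.08 (percentile 83.9). It was below 0 under quantile normalisation, and above the range of the random lists with the 50th and 75th percentile floors (0.18 with either) and with a pseudocount (0.14).

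All 23 measured genes of glycolysis and hypoxia had a higher signal at day 12, and 20 of them by at least 2-fold. Their median log2 ratio was 2.08, at percentile 100 of the matched random lists. The glucose transporter genes Slc2a1 and Slc2a3 were 8.55-fold and 7.41-fold higher. Bnip3, a mitochondrial protein induced by hypoxia, was 7.51-fold higher, Vegfa, the main angiogenic growth factor, 6.80-fold, Pfkfb3, which activates phosphofructokinase, 6.49-fold and the hexokinase gene Hk2 6.43-fold. Pdk1, which holds pyruvate out of the mitochondrial cycle, was 5.58-fold higher. Abundant enzymes differed less, with Pgk1 at 3.0-fold and Ldha at 1.99-fold. Adm was 1.74-fold higher, and Eno2 had a log2 ratio of at least 0.03, from below the floor. Oxidative phosphorylation genes did not move by 2-fold in any of 35 measured members, and their median of 0.11 lay inside the 95% range of the random lists (-0.06 to 0.13).

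Collagen genes of the matrix list differed by less than 2-fold between the days, while 5 genes of collagen-modifying enzymes were at least 2-fold higher at day 12 and others were not. Of 29 measured genes of fibrillar collagen and its processing, 5 were at least 2-fold higher and none 2-fold lower. Their median of 0.21 (percentile 99.97) fell inside the range of the random lists under quantile normalisation (0.04) and after loess (0.09). The 5 higher genes were the prolyl hydroxylase genes P3h2 (8.30-fold), P4ha1 (5.54-fold) and P4ha2 (4.34-fold), the lysyl oxidase gene Loxl4 (4.38-fold, but a log2 ratio of 0.99 in its other probe set and 0.58 with the 75th percentile floor) and the lysyl hydroxylase gene Plod1 (2.42-fold). Loxl3, P4ha3 and Loxl1, of the same enzyme families, had log2 ratios of -0.53, -0.46 and -0.43. Col1a1 went from a signal of 6093 to 9455 (1.55-fold). None of 10 measured small leucine-rich proteoglycans differed by 2-fold in its brightest probe set. Omd had a log2 ratio of 0.44 and Prelp of -0.70, with -1.09 in its other probe set, and the median of 0.13 lay at percentile 86.8 but was below 0 under quantile normalisation and after loess. Among 19 matrix proteases and their inhibitors, the aggrecanase gene Adamts5 was 2.01-fold lower (a log2 ratio of -0.67 in another probe set), and Mmp13, the main collagenase of bone, was 1.54-fold higher (median 0.09, percentile 87.7).

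Chondrocyte markers were lower at day 12. Of 19 measured, 10 were at least 2-fold lower and 1 was at least 2-fold higher, with a median log2 ratio of -1.29 that lay below every matched random list (percentile 0). Matn1, a cartilage matrilin, had a signal of 1507 at day 5 and lay below the floor at day 12, at least 33.6-fold lower. Snorc and Ucma, both made by chondrocytes, were at least 11.5-fold and 10.8-fold lower. The collagen IX genes Col9a2, Col9a3 and Col9a1 were 5.61-fold, 3.54-fold and 2.44-fold lower, Cnmd (chondromodulin) 3.01-fold and the link protein gene Hapln1 2.78-fold. Col2a1, the main cartilage collagen, was 1.89-fold lower and kept a signal of 4439 at day 12. Comp and Sox6 had log2 ratios of 0.07 and 0.50. Ihh, a signal of prehypertrophic chondrocytes, was at least 2.12-fold higher.

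**Figure D3:**
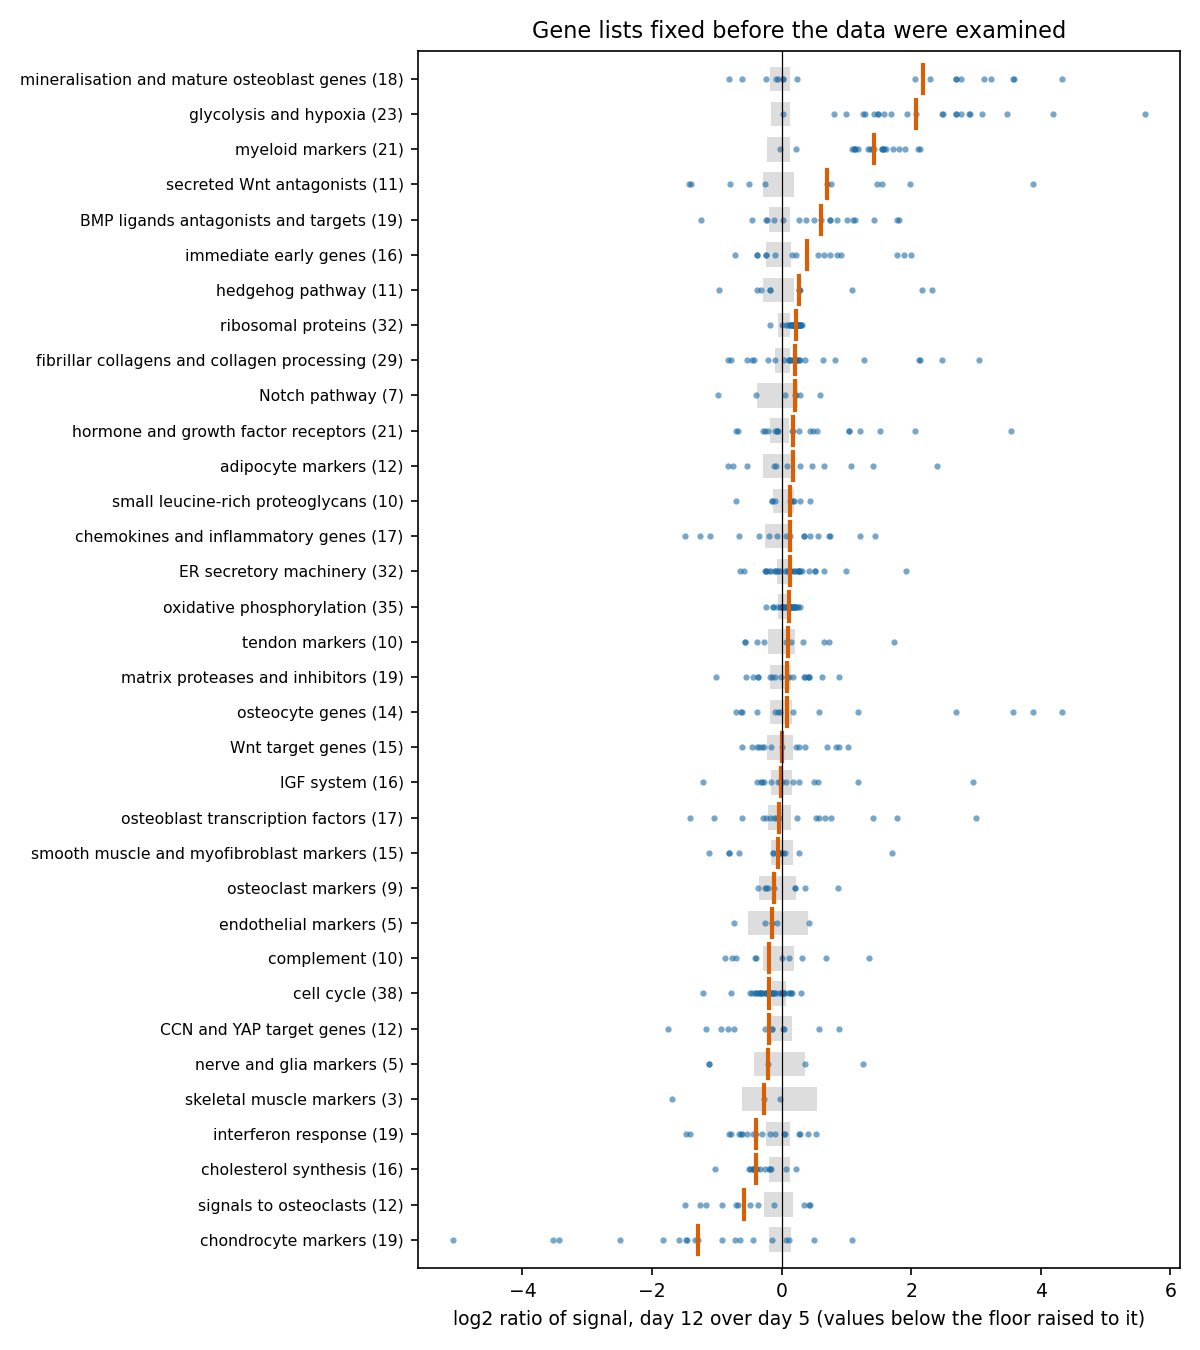
Log2 ratio of signal, day 12 over day 5 (x axis), of each measured gene (points) in the 34 lists with a measured member (y axis, number of genes in brackets). Orange bars mark the list medians and grey bands the central 95% of the medians of 10000 random lists of equal size and signal. The mineralisation, glycolysis and hypoxia, and myeloid lists stand at the top with medians of 2.18, 2.08 and 1.42, and the chondrocyte list at the bottom with -1.29.

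Secreted modulators of Wnt and BMP signalling differed in both directions. Of 11 measured Wnt antagonists, 4 were at least 2-fold higher and 2 at least 2-fold lower. The median of 0.69 (percentile 100) is the bound of Notum, a gene below the floor on 1 array, and was 0.17, inside the range of the random lists, with the 75th percentile floor. Dkk1 was at least 14.7-fold higher by its brightest probe set (its measured probe sets ranged from a log2 ratio of 1.45 to 3.88), Wif1 3.96-fold, Frzb 2.92-fold and Sfrp4 2.77-fold (a log2 ratio of 0.59 with the 75th percentile floor). Sfrp1 was 2.70-fold and Sostdc1 2.62-fold lower. Among 15 Wnt target genes only Tnfrsf19 passed 2-fold (2.03-fold higher, with a log2 ratio of 0.04 in its lowest probe set), Axin2 had a log2 ratio of 0.01, and the median of 0.01 lay at percentile 63.3. Of 19 BMP ligands, antagonists and targets, 6 were at least 2-fold higher, including the receptor decoy gene Bambi (3.51-fold), Bmper (3.42-fold), Bmp8a (at least 2.67-fold) and Bmp2 (2.14-fold). Id4 was 2.37-fold lower and the median was 0.61 (percentile 100), or 0.37 with a pseudocount. In the hedgehog list, Ptch1 (5.01-fold), Hhip (at least 4.50-fold) and the ligand gene Ihh were higher and none of 11 members was 2-fold lower as deposited. Gas1, a hedgehog coreceptor, had a log2 ratio of -0.96 (-1.15 in its other probe set), and 1 member was at least 2-fold lower under quantile normalisation, after loess and with the median of probe sets. Hhip had a log2 ratio of 0.98 in its lowest probe set and 0.21 with the 75th percentile floor. Ptch1 and Hhip are both induced by hedgehog signalling, and Gli1, a further target below the floor at day 5, had a log2 ratio of at least 0.26. The list's median of 0.26 is that bound, lay at percentile 99.4, and was inside the range of the random lists with the 75th percentile floor (-0.18) and with the median of probe sets. No member of the Notch list (7 measured, median 0.21, percentile 95.5) passed 2-fold.

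Of 21 measured hormone and growth factor receptors, 6 were at least 2-fold higher and none 2-fold lower (median 0.18, percentile 99.7). They were Pth1r, Lifr (2.87-fold), Esr1 (at least 2.32-fold, but a log2 ratio of 0.73 with a pseudocount), Lepr (2.06-fold, with a log2 ratio of 0.36 in its lowest probe set), Ptger4 (2.06-fold) and Ramp1, a partner of the calcitonin receptor-like receptor. Ramp1 was 11.6-fold higher by its brightest probe set, and the lowest of its 3 measured probe sets gave a log2 ratio of 0.11. In the IGF list of 16 measured genes, Stc2 was at least 7.77-fold higher (a log2 ratio of 1.36 in its lowest probe set, and just under 2-fold with the 75th percentile floor), Stc1 was at least 2.26-fold higher (a log2 ratio of 0.83 with a pseudocount), and the IGF-binding protein protease gene Pappa was 2.32-fold lower. Their median was -0.01 (percentile 42.2), and was above 0 under median centring and after loess. Of 12 CCN and YAP target genes, Ccn5 was 3.36-fold and Axl 2.24-fold lower and none was 2-fold higher. Their median of -0.20 (percentile 2.52) lay at the lower edge of the range of the random lists as deposited and below it under all 8 alternatives, down to -0.42 without probe sets of shared sequence.

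Of 12 measured signals from osteoblasts to osteoclasts, 3 were at least 2-fold lower at day 12 and none 2-fold higher. Their median was -0.58 (percentile 0), and was -0.34 with a pseudocount and -0.26 with the 75th percentile floor, the last inside the range of the random lists. Of the monocyte attractants, Ccl2 was 2.40-fold lower (a log2 ratio of -0.91 with a pseudocount) and Ccl7 at least 2.81-fold lower, and Efnb2 was 2.25-fold lower. Il34 was 1.89-fold lower. Tnfsf11 (RANKL), the osteoclast differentiation factor, had signals of 73.2 and 44.8, close to the floor, and Tnfrsf11b, its decoy receptor, had a log2 ratio of 0.43. In the interferon list of 19 measured genes, Gbp2 was 2.67-fold lower (a log2 ratio of -0.98 in another probe set) and Gbp3 at least 2.78-fold lower (-0.99 with a pseudocount). The median was -0.39 (percentile 0.08), and -0.23, inside the range of the random lists, with the 75th percentile floor. The chemokine and inflammatory list of 17 held 2 genes higher by at least 2-fold, Tnfaip3 (2.73-fold, but a log2 ratio of -0.016 with the 75th percentile floor) and Ptgs2 (2.30-fold), and 3 lower, Ccl2, Ccl7 and Cxcl5 (at least 2.14-fold), with a median of 0.13 at percentile 96.4, or 0.26 and above the range of the random lists with the median of probe sets. In the complement list of 10, C3ar1, a receptor of myeloid cells, was 2.56-fold higher (a log2 ratio of -0.043 with the 75th percentile floor) beside the myeloid markers' median of 1.42, and Masp1 was 1.84-fold lower (median -0.19, percentile 11.0, or -0.41 and below the range of the random lists with the 75th percentile floor).

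Markers of other cell types showed that myeloid transcripts were present on both days and higher at day 12. Of 21 measured myeloid markers, 19 were at least 2-fold higher and none 2-fold lower, with a median of 1.42 at percentile 100. Tyrobp, a signalling adaptor, was 4.38-fold higher, the Fc receptor gene Fcgr3 4.28-fold, Ms4a7 3.50-fold and Lyz2, the macrophage lysozyme gene, 2.26-fold, from a signal of 2649 to 5984. Cybb was 3.74-fold higher by its brightest probe set, but another gave a log2 ratio of -0.03, and the brightest 0.12 with the 75th percentile floor. Itgam, which encodes CD11b itself, lay below the floor on both arrays, with signals of 14.6 and 35.4. None of 9 measured osteoclast markers passed 2-fold as deposited (median -0.12, percentile 32.6). Atp6v0d2, a proton pump subunit of osteoclasts, was at least 1.84-fold higher, from below the floor, and 1 marker passed 2-fold after loess, with the 50th percentile floor and with a pseudocount. None of 5 endothelial markers passed 2-fold (median -0.15, percentile 35.5).

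Among 12 measured adipocyte markers, Car3 (5.28-fold), Cd36 (at least 2.66-fold) and Lpl (2.11-fold) were higher, while Adipoq, Fabp4 and Pparg had log2 ratios of -0.75 (a bound), -0.83 and -0.54 (list median 0.18, percentile 96.1). That median was above the range of the random lists in 5 of 8 alternatives and -0.045 with a pseudocount. In the smooth muscle and myofibroblast list of 15, Cspg4 was 3.25-fold higher and Cnn1 2.17-fold lower, and Acta2 had signals of 11798 and 12191, a log2 ratio of 0.05 (median -0.06, percentile 22.8). Thbs4 was 3.31-fold higher among 10 tendon genes, but had a log2 ratio of -0.021 with the 75th percentile floor (median 0.10, percentile 81.9, below 0 under quantile normalisation and after loess). Only 3 of 22 skeletal muscle markers were measured, of which Acta1 was 3.23-fold lower, with a log2 ratio of -0.42 with the 75th percentile floor (median -0.27, percentile 21.0). Of 5 nerve and glia genes, S100b and Stmn2 were 2.18-fold and 2.17-fold lower and Tubb3 2.38-fold higher (median -0.22, percentile 18.2). Stmn2 and Tubb3 each stayed under 2-fold with a pseudocount, and the median was -0.94 over 3 genes with the 75th percentile floor. None of the 9 erythroid and lymphoid markers on the array was measured.

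Cell cycle genes stayed bright, with log2 ratios of 0.02 for Mki67 and -0.01 for Top2a. Of 38 measured, 8 had a higher signal at day 12, Ccne1 (2.31-fold lower) was the only one past 2-fold, and the median was -0.20 (percentile 0.12). Cholesterol synthesis genes had a median of -0.39 (percentile 0), with 2 of 16 higher at day 12 and Mvk, mevalonate kinase, 2.05-fold lower (a log2 ratio of -0.68 in another probe set). The secretory machinery list of 32 held 1 gene past 2-fold, Creb3l1 (3.77-fold higher), a transcription factor of collagen secretion, while the chaperone gene Hsp90b1 had a log2 ratio of -0.64. The median of 0.13 (percentile 98.3) was inside the range of the random lists under quantile normalisation, after loess and with the 75th percentile floor. Ribosomal protein genes differed by small amounts, with a median of 0.22 over 32 genes (percentile 99.99, but 0.04 and inside the range of the random lists under quantile normalisation) and none past 2-fold. Among 16 immediate early genes, Klf4 (3.98-fold), Atf3 (at least 3.70-fold) and Ier3 (3.43-fold) were higher and Fos and Egr1 had log2 ratios of 0.66 and -0.38 (median 0.39, percentile 100, or 0.20 with a pseudocount). Of the 34 lists, 11 had a median above the 95% range of their random lists and 5 below it, against 1.70 in all that chance would give if genes of a list moved independently, which they do not. Under every alternative 6 of the 11 stayed above and 3 of the 5 below: mineralisation, glycolysis and hypoxia, myeloid, BMP, receptor and immediate early genes above, and chondrocyte, cell cycle and cholesterol genes below.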

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

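The tests of array scaling, of single cultures, of a lower share of the main cell type and of a fall by 1 factor were chosen after the result was seen, and the second lists were written after the main values but before their own values were looked at. The control probe sets for Gapdh lie outside the main measurement and had a mean log2 ratio of 0.84 (SD 0.07 over 3 probe sets of the same 2 arrays), where the 18 hybridisation controls lay between -0.08 and 0.18. Of 1384 measured probe sets without exactly 1 gene symbol, which no comparison used, 35 were at least 2-fold higher at day 12 and 35 at least 2-fold lower.

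Glycolysis and hypoxia genes were higher at day 12 in 23 of 23 members. Scaling or distortion shared by genes of like signal is argued against, because 95% of random lists matched by signal had medians between -0.16 and 0.13. After loess the list's median was 2.15, above the random lists' range of -0.12 to 0.14. Loess removes only a trend shared by genes of like signal, so that outcome followed from the first comparison. Low oxygen or HIF activity at day 12 is a candidate explanation: in a second list of known targets outside the first, 12 of 14 measured genes were higher and 7 at least 2-fold. The median was 0.96 (percentile 100), and its bootstrap 95% interval of 0.17 to 1.29 only just cleared the random lists' range of -0.22 to 0.15. Kdm3a (log2 ratio 1.53), Tmem45a (1.34), Ddit4 (1.29, also a gene of the amino acid response) and Mif (1.24) were among the higher genes, while Cited2 (-0.77) and Pgm2 (-0.68) were lower. What stays open is a difference between 2 single cultures not tied to the day, such as cell density or time since feeding, since there was 1 array per day.

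Myeloid markers were higher at day 12 although the cultures were started from cells without CD11b. Distortion shared by genes of like signal is argued against, since 95% of signal-matched random lists had medians between -0.22 and 0.12 (the markers' median was 1.51 after loess). A lower share of the main cell type would raise all other cell types alike. The adipocyte (0.18), osteoclast (-0.12) and endothelial (-0.15) medians lay inside their random ranges, far below the myeloid 1.42. These medians cover 12, 9 and 5 measured genes. Another 7 of 19 adipocyte, 5 of 14 osteoclast and 13 of 18 endothelial markers on the array lay below the floor on both arrays. Whether these cell types were present is therefore not known, and their medians cannot decide about a lower share. The chondrocyte markers' median of -1.29 decided the test as set against it. That median is a pattern of its own without a settled cause, so a lower share stays open. A larger share of myeloid cells at day 12 may account for the higher myeloid markers. The quartiles of the 21 markers were 1.14 and 1.61 (a range of 0.47, bootstrap 95% interval 0.21 to 0.77, where probe error gives 0.46), with Cx3cr1 at -0.02 and Aif1 at 0.23 (a bound) outside them. A second myeloid list had a lower median of 0.56 (bootstrap 95% interval 0.19 to 0.95) over the 15 measured of its 25 genes on the array. That median was still above the random lists' range of -0.29 to 0.18, with 13 genes higher, 4 of them at least 2-fold, and 2 lower. Several of the genes were bounds near the floor, which shrinks their ratios. A larger share and higher expression per myeloid cell therefore cannot be told apart. A difference between single cultures not tied to the day also stays open, since there was 1 array per day. The brightest of the myeloid genes, Lyz2 and Lyz1, had signals of 2649 and 4021 at day 5, and the CD11b-negative gate at the start would remove cells that carry CD11b.

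Chondrocyte markers were lower at day 12. Against signal-matched random lists, 95% of which had medians between -0.19 and 0.14, distortion shared by genes of like signal is argued against. The markers' median after loess was -1.23. A fall of all chondrocyte markers by 1 factor could not be decided. The interquartile range of their log2 ratios was 1.41 (bootstrap 95% interval 0.76 to 3.03) where probe error gives 0.32, so the ratios varied more than probe error gives. Probe error leaves out differences between cultures and the shrinkage of ratios at the floor, which also widen or narrow that range. Loss of cartilage cells together with expression of some markers in other cells stays possible and was not tested. With 1 array per day, a difference between single cultures not tied to the day stays open here too. A wider fall of cartilage genes could not be decided: a second list had a median of -0.038 (bootstrap 95% interval -0.48 to 1.06), with Susd5, Runx3 and Trps1 higher by log2 ratios of 1.57, 1.24 and 1.06 and Col27a1 and Wwp2 at -0.65 and -0.61.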

How the results depend on the processing

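No paired analysis was possible because there was 1 array per day, and leaving out a replicate was not possible for the same reason. The count of genes at least 2-fold higher (373) stayed between 296 and 510 under 7 of 8 alternatives and was 223 with the 75th percentile floor. The count of lower genes (181) stayed between 140 and 178 under 5 of them and was 297 with the 50th percentile floor, 74 with the 75th and 99 with a pseudocount in place of the floor. The floor's own construction gives these shifts, since it sets how many dim genes enter and how far a ratio is shrunk. A 3-fold threshold gave 175 higher and 36 lower genes and a 1.5-fold threshold 760 and 807, so that the excess of higher genes does not hold at 1.5-fold. Scaling moved the counts to 403 and 151 (median centring), 388 and 157 (quantile) and 422 and 140 (loess). Median centring shifted the median of all measured genes by 0.05, and after loess that median was 0.01.

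Of 272 shares of list members higher at day 12, 9 left the interval of the deposited scaling. These intervals cover the number of genes and are wide for short lists, such as 0.5% to 71.6% for 5 endothelial markers. A share that stayed inside therefore says little about the effect of processing. Myeloid markers reached 100% under median centring, quantile normalisation, loess and the 75th percentile floor. Endothelial markers fell to 0% with the 75th percentile floor (1 gene), the median of probe sets and without probe sets of shared sequence. Under quantile normalisation the share was 60% for oxidative phosphorylation and 75% for ribosomal proteins, whose medians ranged from 0.02 to 0.16 and from 0.04 to 0.27. The cause was not tested. List medians ranged from 1.17 to 2.23 for mineralisation, 1.89 to 2.48 for glycolysis and hypoxia, 1.23 to 1.55 for myeloid and -1.29 to -0.90 for chondrocyte markers. Against random lists drawn under the same setting, 6 of the 11 lists above the 95% range and 3 of the 5 below it stayed there under all 8 alternatives. Collagen, secretory machinery and ribosomal genes moved inside under quantile normalisation, and Wnt antagonists, hedgehog, signals to osteoclasts and interferon genes with the 75th percentile floor. CCN and YAP targets lay below the range in all 8 alternatives and adipocyte markers above it in 5. Osteocyte genes lay above it in 3, Notch (pseudocount) and chemokine genes (median of probe sets) in 1 each, and complement, nerve (both 75th percentile floor) and skeletal muscle genes (pseudocount) below it in 1 each. Medians near 0 changed sign in 1 or 2 settings for osteoblast transcription factors, osteocyte genes, proteoglycans, Wnt targets, hedgehog, IGF, adipocyte, osteoclast, tendon and complement genes. Of 98 named genes past 2-fold, 72 stayed past it under every alternative in which they were measured, and 26 did not. A gene not measured under an alternative was not counted there, so the 72 can include genes that a higher floor removed. With the 75th percentile floor Acta1, Ada, C3ar1, Cybb, Gbp2, Hhip, Loxl4, Lrrc75b, Mepe, Otor, Sfrp4, Stc2, Stmn2, Thbs4 and Tnfaip3 fell below 2-fold, and under other alternatives Adamts5, Ccl2, Esr1, Gbp3, Msx1, Mvk, Panx3, Ramp1, Stc1, Tnfrsf19 and Tubb3. The log2 ratios of C3ar1 (-0.043), Thbs4 (-0.021) and Tnfaip3 (-0.016) changed sign with the 75th percentile floor, by its construction, since it raises dim values to unequal floors. Panx3 fell to 0.28 without probe sets of shared sequence, and Ramp1 and Cybb to 0.65 and 0.28 with the median of probe sets.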

Other observations

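The patterns in this part were picked after the main values were seen, while the lists that test them were written before their own values were looked at. Several genes known to respond to amino acid shortage and other stress were higher at day 12. Chac1, which degrades glutathione, was 5.90-fold higher, Trib3 at least 4.56-fold, Atf3 at least 3.70-fold and Ddit3 1.99-fold. An amino acid response is a candidate explanation. In a separate list of 25 measured genes 20 were higher, but only 2 of them by at least 2-fold. The list's median log2 ratio was 0.39 (bootstrap 95% interval 0.21 to 0.54, percentile 100 of matched random lists). Nupr1 (1.58), Slc7a5 (0.84), Eif4ebp1 (0.84) and Asns (0.68) were among the higher ones, and Aars, Wars, Cebpb, Sesn2 and Phgdh had log2 ratios between -0.29 and -0.16. The metallothionein genes Mt1 and Mt2, which bind zinc, were 5.42-fold and 3.45-fold higher.

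Imprinted growth regulators were among the bright genes that were lower at day 12. Meg3 was 2.60-fold lower, Cdkn1c, a cell cycle inhibitor, 2.44-fold and Peg3 2.19-fold. Whether a joint fall of imprinted genes may underlie this was not settled: in a separate list of 11 measured genes 7 were lower and 4 higher, with a median of -0.40, below the random lists' range of -0.19 to 0.20, but its bootstrap 95% interval of -0.54 to 0.09 reached into it. Rian and Mirg (a bound), transcribed next to Meg3, had log2 ratios of -0.88 and -0.89, Ndn -0.54, Dlk1 -0.51 (a bound), Sgce and Zim1 (a bound) -0.40, and Plagl1 -0.37, while Mest, Grb10, Gnas and Slc38a4 lay between 0.02 and 0.19, and the lowest probe sets of Grb10 and Slc38a4 were below 0.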
